A study of Mus musculus with 9 samples.

How the data were processed

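MicroRNA (miRNA) levels were measured in whole lungs of mouse embryos at embryonic day 18.5 on a NanoString nCounter mouse miRNA panel, which counts individual reporter-labelled molecules without amplification. The labels describe 5 wild type lungs and 4 lungs homozygous for a mutated 3′ untranslated region (3′UTR) of Bim, all C57BL/6. Per the labels' protocols, total RNA was extracted from frozen, ground tissue with a miRNA kit and 100 ng per sample was run.

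The deposited values were raw counts per probe, and no background step, filter or normalization is given in the sources used here. The deposited count table held 626 probes: 566 for mouse miRNAs, 33 for viral miRNAs, 4 for housekeeping mRNAs, 8 negative controls, 6 positive controls, 6 ligation controls and 3 spike-in probes. A second deposited table gave the same counts lane by lane, per the file headers for 12 lanes of 1 cartridge, because samples 1, 5 and 6 had each been run in a second lane. All 5634 values of the count table equalled those of each sample's first lane, and the first lane was used throughout. Repeat lanes count as 1 replicate. Because panel probes rather than reads were counted, no aligner and no genome build entered, and no coordinates are given.

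Wild type replicates were numbered 1 to 5 and mutant replicates 6 to 9 in the labels. The lane table's comment entry for sample 5 reads as mutant in both of its lanes, which gives 4 wild type and 5 mutant samples, against 5 and 4 in the sample labels and the series design. The sample labels were followed, and results with sample 5 counted as mutant are given as an alternative. Litter, sex and dissection day are not given in the sources used here, so p-values measure the spread between these samples only.

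A mouse miRNA probe was kept if its count lay above the mean plus 2 SD of the 8 negative controls of the same lane in at least 4 samples. This kept 189 of 566 probes, of which 112 passed in all 9 samples, while 298 passed in none. None of the 33 viral probes passed. Library sizes and tests used the mouse miRNA probes alone. Differential levels were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, glmQLFit and glmQLFTest, no covariate) and adjusted by Benjamini-Hochberg over the 189 probes at 0.05. Log2 CPM values used a prior count of 2.

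The 22 lists of miRNAs (clusters, families and cell type markers) were fixed before the data were examined. A list was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 if at least 3 of its probes were kept, which left 17 lists. The 5 others were the miR-34 family, neural, liver, embryonic stem cell and hypoxia lists. The score of a list in a sample was the mean log2 CPM of its kept probes. Shares of counts, detected probes, totals, control counts and list scores were compared with exact two-sided permutation tests over the 126 splits of 9 samples into 5 and 4, which cannot give a p below 0.00794.

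Probes are named by a rule fixed before the data were examined: every kept probe of the miR-17~92 cluster and its paralogs, the 10 probes with the smallest p among those higher and the 10 among those lower in the mutant whether or not they passed, the most abundant and the smallest-p member of each other list, and the 5 most abundant probes. A probe that detects several miRNAs carries all their names. Probes named outside this rule were chosen after their values were seen, and this is said where they appear.

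Alternatives set before the data were examined were DESeq2 1.42.0, scaling by the 100 most abundant probes, by positive controls, by housekeeping mRNAs or by total count, no filter, a filter in all 9 samples, background subtraction, voom, limma on log2 of the count plus 1, leaving out each sample, camera with an estimated correlation, fry, and other definitions of share and detection. Alternatives added after seeing the data left out samples 3 and 8, left out samples 3, 5 and 8, counted sample 5 as mutant, used summed or lower-background lanes, or took the log2 mean negative control count of the lane as a covariate. The fits were tested on simulated data drawn from the means and spread of the 189 probes. In 20 simulations of all 9 samples, 21.8% of probes changed 1.5-fold, 66% of those changed 2-fold and 97% of those changed 4-fold were recovered. Without samples 3 and 8 these shares were 65.5%, 94% and 99.8%. Each simulation changed 20 probes at each of these folds at once, and probes were drawn independently. With fewer changed probes the recovered shares could be lower. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.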

Results

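The lungs of 9 mouse embryos were profiled, 5 wild type and 4 homozygous for the Bim 3′UTR mutation. Bim (Bcl2l11) is a pro-apoptotic BH3-only protein, and its 3′UTR carries seed matches of the miR-17~92 cluster that this allele changes. The panel reads miRNAs, so Bim mRNA was not analysed here and the allele itself could not be checked in the counts. Mouse miRNA probes gave 206964 to 289227 counts per sample. The mean negative control count ran from 28.1 to 79.1, and 129 to 236 miRNA probes per sample exceeded the background threshold of their lane.

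The fetal lung profile was led by miR-126-3p, an endothelial miRNA, at 11.5% ± 1.65 of kept counts (SD, n = 9). It was followed by miR-16 with 6.44% ± 0.962, let-7d with 5.95% ± 0.630, miR-125a-5p with 4.36% ± 0.489 and let-7i with 3.90% ± 0.348. These 5 probes together held 32.1% ± 2.64 of the counts. Without the samples set apart in the next paragraph, miR-126-3p held 12.2% ± 0.526 and these 5 probes together 33.3% ± 0.561 (SD, n = 7).

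Wild type 3 and mutant 8 stood apart from the other 7 samples in their tissue markers. Cardiac and skeletal muscle miR-1 reached 9153 counts in wild type 3 and 14021 in mutant 8, against 66 to 147 in the others. The probes miR-133a, miR-208a, miR-208b and miR-499, named after their values were seen, followed the same pattern, with miR-208b at 3750 and 5797 counts against 33 to 82. Epithelial miR-200c was low in both, at 173 and 380 counts against 2495 to 3356. The first principal component of the 189 kept probes held 76.9% of the variance and separated these samples from the rest. Because each genotype held 1 such sample, every result below is also given without them where its call changes.

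**Figure D1:**
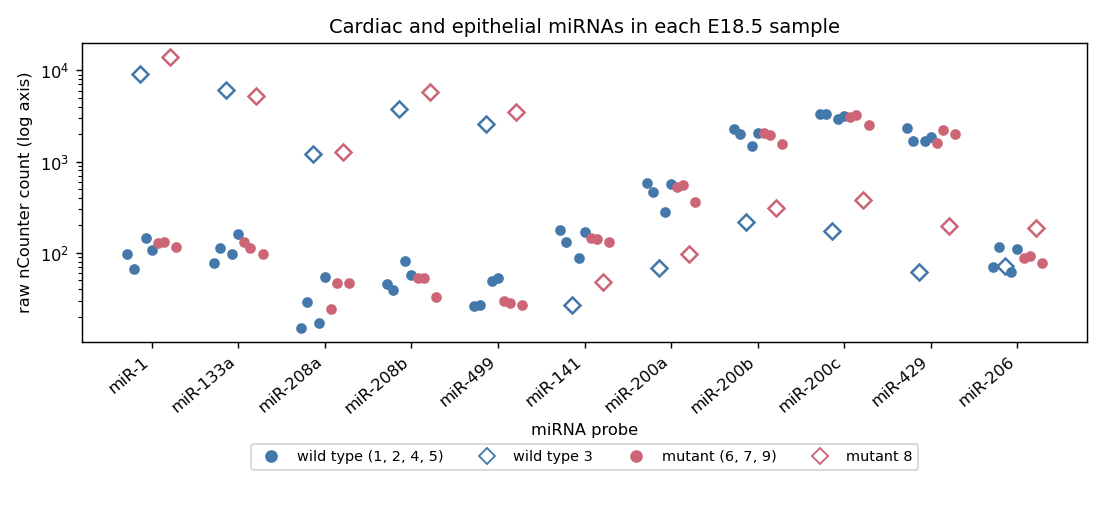
Raw nCounter counts on a log axis for 5 cardiac miRNAs, the 5 miR-200 family members and miR-206 in each of the 9 samples. Open diamonds are wild type 3 and mutant 8, where miR-1 reached 9153 and 14021 counts while the other 7 samples lay between 66 and 147.

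The first comparison asked which miRNAs differ between wild type and mutant lungs. The probes with the smallest p included 2 members of the miR-17~92 cluster, miR-19b and miR-19a, which read 1.47-fold and 1.50-fold higher in the mutant. Their log2 fold changes were 0.55 ± 0.19 and 0.58 ± 0.23 (SE, 5 against 4). miR-204 had a log2 fold change of -0.41 ± 0.16 and let-7d of -0.27 ± 0.12. miR-142-3p, a haematopoietic miRNA, had the largest value among these at 1.33 ± 0.56, and its value was 0.17 ± 0.21 without samples 3 and 8. No probe passed Benjamini-Hochberg adjustment in edgeR's quasi-likelihood test (0 of 189, smallest adjusted p = 0.997). At an unadjusted p under 0.05 there were 5 probes, 3 higher and 2 lower, where 9.45 would arise by chance, and DESeq2 gave 0 adjusted and 9 unadjusted. Without samples 3 and 8, edgeR gave 0 adjusted and 6 unadjusted, let-7d stood at -0.13 ± 0.09 and miR-18a at 0.24 ± 0.24. Of the 48 named probes, 6 changed sign and 18 had a log2 fold change smaller by over 1.5 times in that fit.

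Among the other probes with small p, none of which passed adjustment, miR-296-5p, miR-138, miR-340-5p, miR-374 and miR-2132 read higher in the mutant, with log2 fold changes of 0.30, 0.31, 0.44, 0.27 and 0.31. Those that read lower were miR-30c, miR-543, miR-676, miR-223, miR-433 and miR-27a, at -0.39, -0.35, -0.26, -0.41, -0.26 and -0.23. let-7i and miR-126-3p, both among the most abundant miRNAs, had values of -0.20 ± 0.13 and -0.20 ± 0.14. Without samples 3 and 8 these were -0.12 ± 0.13 and -0.08 ± 0.08.

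The second comparison asked whether the miR-17~92 cluster, whose seed matches the allele changes, differs as a group. Of the 6 cluster probes on the panel, miR-92a did not pass the background filter, so it is not part of this result. All 5 kept probes of the cluster read higher in the mutant, with a mean log2 fold change of 0.39, which was 0.25 without mutant 9. The combined probe for miR-106a and miR-17 gave 0.26 ± 0.20, miR-18a 0.41 ± 0.23, and the combined probe for miR-20a and miR-20b 0.16 ± 0.24. miR-18a was kept but lay near background, under its lane threshold in wild types 2, 3 and 5 and in mutant 6. The combined probes also belong to the paralog list, so the lists overlap. In camera the cluster list passed at an adjusted p of 0.00013 with the preset correlation, and it did not pass with an estimated correlation (adjusted p = 0.715). Among its members 0 passed over all probes and 0 when adjusted over the list alone.

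The list score of the cluster was 11.42 ± 0.15 in the wild type (SD, n = 5) and 11.78 ± 0.39 in the mutant (n = 4), with an exact two-sided permutation p of 0.103. Mutants 7, 8 and 9 lay above the highest wild type score of 11.66, while mutant 6 was at 11.28. Samples 2, 5 and 6 were run in lanes with a mean negative control count of 64.3 to 79.1, against 28.1 to 39.5 in the other lanes. In the lower-background lanes the score was 11.49 ± 0.15 in 3 wild types and 11.95 ± 0.25 in 3 mutants, an exact permutation p of 0.1, which is the smallest this design allows. This split by lane background was made after the data were seen. It leaves mutant 6 out of the lower-background lanes and keeps samples 3 and 8 in them. The separation was narrow, with wild type 4 at 11.66 and mutant 7 at 11.67. The higher-background lanes held 2 wild types at a mean of 11.30 and 1 mutant at 11.28. Counting sample 5 as mutant brought the cluster's mean log2 fold change to 0.25 and ended the camera call (adjusted p = 0.177). Without samples 3, 5 and 8 the mean was 0.27 (adjusted p = 0.0539).

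**Figure D2:**
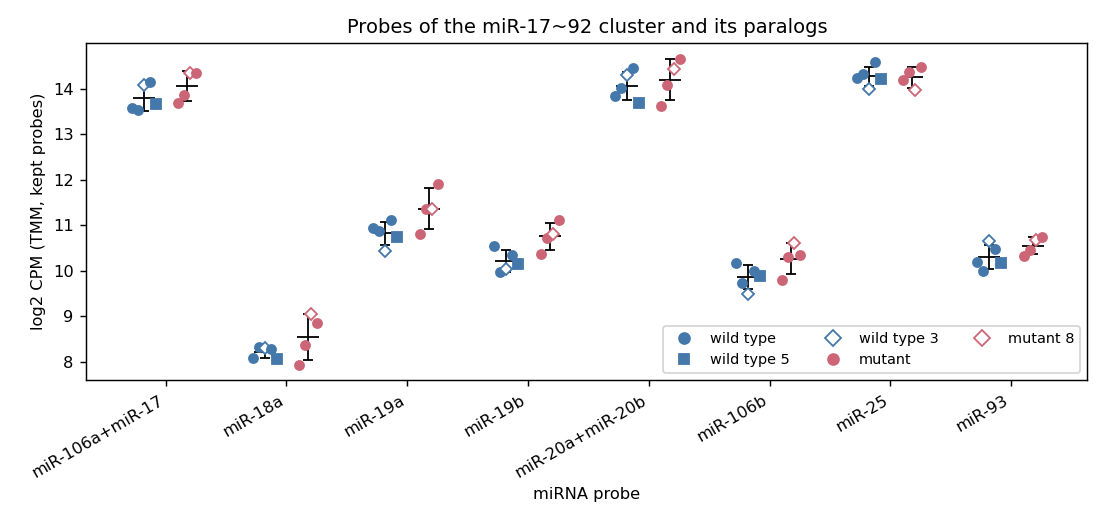
Log2 CPM of each miR-17~92 cluster and paralog probe in the 9 samples, wild type in blue and mutant in red, with bars for the group mean ± SD. The groups overlap for every probe, and miR-19b has the smallest p with a log2 fold change of 0.55 ± 0.19 (SE).

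The paralog clusters miR-106b~25 and miR-106a~363 had a mean log2 fold change of 0.21 over 5 kept probes, 4 of them higher in the mutant. For miR-106a~363 only the combined probes shared with the cluster list were kept, so nothing specific to it was read. miR-106b gave 0.42 ± 0.20 (0.21 ± 0.17 without samples 3 and 8), miR-93 gave 0.25 ± 0.17 and miR-25 gave -0.02 ± 0.16. The list did not pass (adjusted p = 0.063), and its adjusted p was 0.971 with an estimated correlation. At the preset correlation it passed in 10 of 28 alternatives. Its mean was 0.12 without mutant 9. Together, cluster and paralog probes held 5.59% ± 0.760 of kept counts in the wild type (SD, n = 5) and 6.54% ± 1.14 in the mutant (n = 4). The difference of 0.947 percentage points lay between the SDs of the groups, with an exact two-sided permutation p of 0.167. Within the lower-background lanes, which hold samples 3 and 8 but not mutant 6, the share was 5.75% ± 1.03 in 3 wild types and 6.90% ± 1.07 in 3 mutants (exact permutation p = 0.2). In the higher-background lanes it was 5.35% in 2 wild types and 5.44% in 1 mutant. Without mutant 9 the difference was 0.479 points (exact permutation p = 0.393). Without wild type 4 it was 1.28 points, with an exact permutation p of 0.0286, the smallest that 4 against 4 samples give.

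The third comparison asked whether other miRNA groups, among them markers of lung cell types, differ by genotype. None of the other 15 lists passed, with adjusted camera p-values from 0.684 to 0.998. Scaling by housekeeping mRNAs shifted all probes, moving the median of the 189 from -0.03 to 0.11, so the signs of the small negative list means (let-7, Dlk1-Dio3, miR-200, endothelial, erythroid, Sfmbt2, miR-322 and injury) hold only relative to the scaling used. Of the 9 let-7 family probes 2 read higher and 7 lower, with a mean log2 fold change of -0.07. Over all 189 probes 40.2% read higher (71.4% with housekeeping scaling), which is the measure for such counts. In the Dlk1-Dio3 imprinted cluster 10 of 26 probes read higher and 16 lower, with a mean of -0.07, and 6 and 20 without samples 3 and 8. This list passed in camera without wild type 3 alone, at a mean of -0.14 (adjusted p = 0.00457), a fit for which no correlation was estimated. Wild type 3 and mutant 8 both scored low on it, at 9.59 and 9.66, so that fit leaves mutant 8 unmatched. The list did not pass without both (adjusted p = 0.0813), but passed when sample 5 was also left out (adjusted p = 0.0449) or counted as mutant (adjusted p = 0.0444), again with no correlation estimated. The miRNAs reported to act on Bim outside the cluster had 3 probes higher and 1 lower (2 and 2 without samples 3 and 8), with miR-24 at 0.23 ± 0.22 and miR-181a at -0.16 ± 0.15.

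Among cell type lists, the miR-200 family of epithelium had 2 probes higher and 3 lower, with a mean of -0.05. Its score was 9.01 in wild type 3 and 9.44 in mutant 8, and 11.77 to 12.09 in the other 7. The ciliated, basal and neuroendocrine list had 1 probe higher and 3 lower, with miR-205 at 0.63 ± 0.41, or 0.23 ± 0.19 without samples 3 and 8. For this list the mean, 0.09, and the median, -0.05, differed in sign. The endothelial list had 2 higher and 3 lower, with a mean of -0.01, and the smooth muscle and mesenchyme list had 3 higher and 2 lower, with miR-199a-3p at -0.26 ± 0.30. In the myeloid and lymphoid list 1 probe was higher and 5 lower, and the mean of 0.05, which rested on miR-142-3p, opposed the median of -0.16. The erythroid list had a mean of -0.08 while its camera direction was up, with miR-451 at -0.21 ± 0.22 and miR-144 at 0.30 ± 0.26. The cardiac and skeletal muscle list had a mean of 0.13, with miR-1 at 0.43 ± 2.00 and miR-206 at 0.33 ± 0.29 (0.26 ± 0.29 and -0.01 ± 0.22 without samples 3 and 8).

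The cluster around miR-322 had the smallest permutation p of the 17 list scores, at 11.06 ± 0.13 in the wild type (SD, n = 5) and 10.90 ± 0.08 in the mutant (n = 4), with an exact two-sided p of 0.0635, or 0.877 after adjustment over the lists. The miR-29 family had a mean of 0.07 (miR-29a 0.08 ± 0.32, miR-29c 0.08 ± 0.23), but all 3 of its probes read lower without samples 3 and 8, with a mean of -0.17. In the repeat lanes of the same RNA, miR-29c read higher in each higher-background lane, by 0.59 log2 on average. miR-29a did so in samples 1 and 5 but not in 6. Lane background was not separated from genotype for this family. The other means were, for the miR-15/16 family, 0.10 (miR-16 0.20 ± 0.12) and, for the cluster around miR-322, -0.13 (miR-322 -0.28 ± 0.34, miR-351 -0.20 ± 0.17). The Sfmbt2 intronic cluster had a mean of -0.13, with miR-669a at -0.39 ± 0.31 and the combined miR-466a-3p and miR-466b-3-3p probe at -0.05 ± 0.17. miR-669a also read higher in the higher-background lane of each repeat pair, by 0.83 log2 on average, and the combined probe did not. The injury and inflammation list had a mean of -0.05, with miR-146a at -0.16 ± 0.52 and miR-146b at -0.26 ± 0.20. Lists with too few kept probes for a test gave miR-34a at 0.05 ± 0.20, miR-218 at 0.13 ± 0.21, miR-122 at -0.00 ± 1.15 and miR-210 at -0.11 ± 0.39. miR-200c was at -0.15 ± 0.72, miR-382 at -0.13 ± 0.28 and miR-125a-5p at -0.19 ± 0.14 (-0.02 ± 0.11 without samples 3 and 8).

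**Figure D3:**
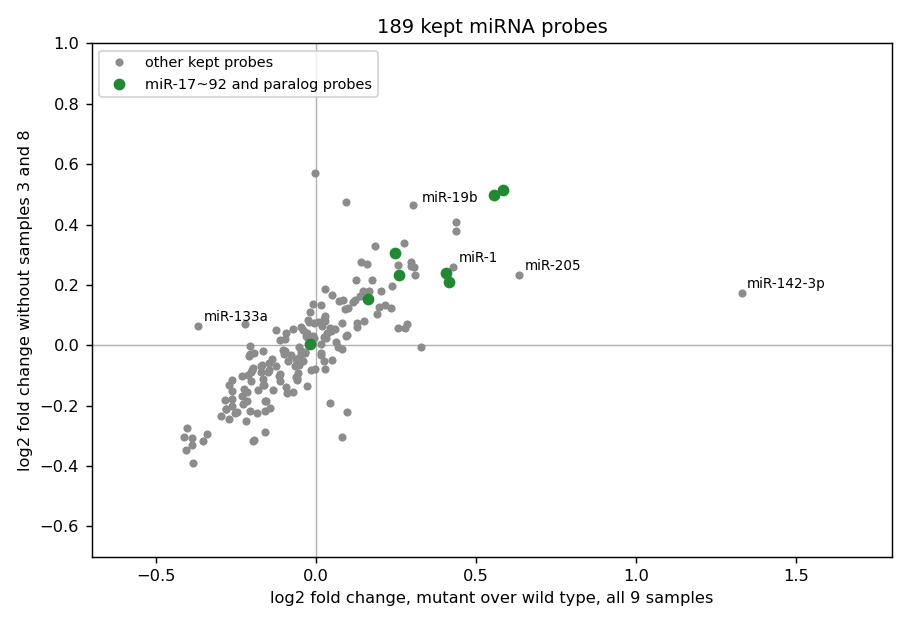
Log2 fold change, mutant over wild type, of the 189 kept probes with all 9 samples (horizontal axis) and without samples 3 and 8 (vertical axis). miR-142-3p moves from 1.33 to 0.17, while miR-19b stays at 0.55 and 0.50; none passes adjustment in either fit.

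The groups did not differ in how much was measured by the tests run. Detected miRNA probes numbered 172.4 ± 36.6 in the wild type (SD, n = 5) and 186.3 ± 40.1 in the mutant (n = 4), with an exact two-sided permutation p of 0.595. Mouse miRNA totals were 254942 ± 38114 and 253985 ± 15825 (exact permutation p = 0.96). Mean negative control counts were 48.1 ± 22.4 and 43.6 ± 15.6 (exact permutation p = 0.794), positive control geometric means 1553 ± 205 and 1459 ± 67.6 (exact permutation p = 0.452), and TMM factors 0.981 ± 0.0624 and 1.03 ± 0.0543 (exact permutation p = 0.278).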

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

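All tests of explanations in this part, the splits of the samples included, had their outcomes written down only after the results were seen, and the tests of heart and skeletal muscle were revised after that.

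Several values lay far from the rest of their group. By a gap test for single outliers, 32 values in 158 tested groups were marked, 18 in wild type 3 and 11 in mutant 8. Chance marks about 1 in 20 groups. The marks cannot be set against that rate, since miR-133a, miR-208a, miR-208b and miR-499 were chosen after their values were seen and list scores share probes with single miRNAs. In wild type 3, counts were high for miR-208a (1202), miR-208b (3750), miR-499 (2602), miR-133a (6016) and Gapdh mRNA (1663), and low for Actb mRNA (2773). In mutant 8 they were high for miR-208a (1271), miR-208b (5797), miR-499 (3460) and miR-133a (5201). The gap test did not mark Gapdh (1349) and Actb (4329) mRNA in mutant 8. These also lay outside the other 7 samples, at 336 to 533 and 8058 to 10941. Both are among the 4 mRNAs of the housekeeping scaling. Log2 CPM in wild type 3 was 15.74 for miR-1, 12.25 for miR-122 and 11.57 for miR-210 at the high end. At the low end it was 10.03 for miR-200c, 9.39 for miR-205, 14.18 for miR-322, 10.01 for miR-146a and 10.59 for miR-433. In mutant 8 it was 15.86 for miR-1, 12.16 for miR-142-3p and 9.64 for miR-206 at the high end and 10.66 for miR-200c at the low end. List scores of wild type 3 stood apart for the miR-200 family (9.01), ciliated, basal and neuroendocrine epithelium (8.37), cardiac and skeletal muscle (13.21) and the Dlk1-Dio3 cluster (9.59). Those of mutant 8 did so for the first 3 of these (9.44, 9.28 and 13.31). The 3 values from other samples were the miR-17~92 share of 6.94% in wild type 4, the let-7 score of 14.01 in wild type 5, and the combined miR-466a-3p and miR-466b-3-3p probe at 9.69 in mutant 9. Outside the tested probes, mutant 8 exceeded every wild type in miR-208a (1271), miR-208b (5797), miR-499 (3460) and miR-10b (131).

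Cardiac miRNAs in wild type 3 and mutant 8 form the first pattern weighed. Most counts of these miRNAs in the other 7 samples lay at background, so ratios were taken against the highest count or lane threshold among them and are lower bounds: at least 15.3 as the median over the 7 members of the fixed muscle list, and at least 6.08 to 71.0 for 5 members singled out after their values were seen. Heart tissue is a candidate source. In both samples miR-133b and miR-206 did not exceed that level. The list holds miRNAs of cardiac and of skeletal muscle, so its median cannot separate the tissues. Skeletal muscle stays open (miR-206 at 0.612 times the highest other count in wild type 3 but 1.61 times in mutant 8, where that count lay below its own lane threshold), while a failed lane is argued against by positive controls 1.13 times the lowest other sample, and genotype by such a sample in both labelled genotypes, 2 of 2. A whole heart under a lung label and heart tissue mixed into a lung cannot be told apart, since the miR-200 family stayed at a median 4.43% of the other samples in wild type 3 and 14% in mutant 8 and no heart sample is at hand.

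The higher miR-17~92 probes in the mutant form the second pattern, for which chance could not be excluded. Of 100 splits of the 9 samples, 7 gave a camera p as small (real 7.63e-06, smallest other 3.56e-08). So did 7 of 35 splits without samples 3 and 8 (real 0.000255, smallest other 1.49e-05). Both counts include the real split, and splits with the cluster lower as well as higher. At least as many lists passed in 81 of 100 splits, the real one again included (real 1, highest other 6). The score difference was 0.36 ± 0.19 (SE), 0.34 ± 0.16 with lane background as a covariate, 0.29 ± 0.24 without samples 3 and 8, and 0.13 ± 0.27 when sample 5 was also counted as mutant. Adding lane background as a covariate and leaving out samples 3 and 8 each moved the estimate little. The preset camera call stayed with the background covariate (0.36) and without these samples (0.33). Without these samples, camera with an estimated correlation ended it (adjusted p = 0.728). The small moves gave no sign that lane background or samples 3 and 8 are the whole cause, but the intervals are too wide to exclude them. All 95% intervals of the score include 0, so these, the group of sample 5 and genotype stay open; this interval rule replaced one of 2 SE after the values were seen, under which lane background as the whole cause was argued against.

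The real count of 0 differential probes is met by any split (100 of 100) and tests nothing, but samples 2, 3, 5 and 6 against the rest called 21, which points to a structure of the samples. The third pattern is therefore samples 2, 5 and 6 against 4, 7 and 9, defined by lane background and not by genotype, a split that called 54 probes, 35 higher and 19 lower in the higher-background lanes. Called probes had a median count of 154, against 264 for the uncalled ones. Lane thresholds in samples 2, 5 and 6 were 147 to 198, so many called probes lay near background. The lower probes included miR-19a (-0.70), miR-19b (-0.58), miR-106b (-0.42) and miR-93 (-0.39). They also included the combined probes for miR-20a and miR-20b (-0.63) and for miR-106a and miR-17 (-0.50). miR-18a and miR-25 were not called. Mutants 7 and 9 lay on the lower-background side and mutant 6 on the other. For these probes the split therefore cannot fully separate lane from genotype. Sample 1, left out of this split, was run in a lane of each kind. Of the 54 probes, 47 (87.0%) moved the same way between its lanes of the same RNA. That share counts direction and not size. Between its lanes miR-19a moved by -0.34, miR-19b by -0.36, miR-106b by -0.34 and miR-93 by 0.07. The combined probe for miR-20a and miR-20b moved by -0.20 and that for miR-106a and miR-17 by -0.02. Each of these shifts was smaller than in the split. Lane background is a candidate cause, from 1 lane pair whose probes are not independent, so the share carries no error for the lane effect. No biological explanation was tested, since samples 2, 5 and 6 share no labelled group.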

How the results depend on the processing

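The alternatives with samples 3, 5 or 8 left out together or regrouped, with other lanes or a background covariate, and the permutation of list scores were added after seeing the data. The number of differential miRNAs was 0 in all 28 alternatives, with 2 to 14 probes at an unadjusted p under 0.05. The miR-17~92 cluster list kept its direction in all 33 and its call in 25 (adjusted p 6.71e-06 to 0.859), with mean log2 fold changes of 0.25 to 0.54 when single samples were left out, lowest without mutant 9. It lost the call without samples 3, 5 and 8 (0.27), with sample 5 as mutant (0.25, or 0.16 without samples 3 and 8), with an estimated correlation or fry (0.39 each), with an estimated correlation without samples 3 and 8 (0.33), and in exact permutation of its score (0.36, or 0.29 without samples 3 and 8). The paralog list passed with scaling by the top 100 probes (0.22), positive controls (0.33), housekeeping mRNAs (0.35) or total count (0.28), with no filter (0.35), a strict filter (0.24), voom (0.21) and limma on unscaled counts (0.28), all at the preset correlation; its adjusted p was 0.971 with an estimated correlation and 0.859 in fry. When single samples were left out it ranged from 0.12 to 0.31, passing without wild type 4 (0.28) or mutant 6 (0.31). The number of lists past the threshold was 1 or 2 when single samples were left out. It was 2 under each scaling and filter just named and with sample 5 as mutant without samples 3 and 8, and 0 with sample 5 as mutant, with an estimated correlation (with or without samples 3 and 8) and with fry. The cause was not tested. Scaling by housekeeping mRNAs moved the median log2 fold change of all probes from -0.03 to 0.11.

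The share of counts differed by 0.479 to 1.31 points when single samples were left out, lowest without mutant 9, and passed without wild type 4 (1.28). Uncalled differences changed sign in some settings. Detected probes ranged from -2.73 to 28.9 with single samples left out, and were -11.3 without samples 3, 5 and 8, -8.45 with sample 5 as mutant and -21.5 with that and without samples 3 and 8. Mouse miRNA totals ranged from -12952 to 7614, and were 14662 and 3927 in the last 2 of these settings. Mean negative control counts ranged from -12.2 to 3.28, and were 5.33, 10.4 and 13.5 in these 3 settings. The cause was not tested. Of 1331 fits of the 48 named probes 0 were called and 81 changed sign. Of 458 fits of the other 15 lists 97 changed sign without a call and 4 passed, let-7 at -0.10 and Dlk1-Dio3 at -0.09 with sample 5 as mutant without samples 3 and 8, and Dlk1-Dio3 at -0.09 without samples 3, 5 and 8 and at -0.14 without wild type 3. In simulated data of all 9 samples 21.8% of 1.5-fold changes were recovered, so changes of that size can be missed. No paired analysis was possible because the groups share no replicate number.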

Other observations

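The test described in this part was made after the data were seen, and the values below belong to no comparison between genotypes.

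In wild type 3 and mutant 8 other miRNAs moved beside the cardiac ones. miR-378 gave 1672 and 1775 counts against 172 to 229 in the other 7 samples, miR-149 365 and 379 against 47 to 111, and miR-486 541 and 494 against 109 to 225. Ciliated-cell miR-449a gave 58 and 70 counts against 788 to 1307, and miR-10a 58 and 80 against 552 to 668. Smooth muscle miR-145 was similar across samples, at 5066 and 6299 counts against 4504 to 7206. The liver miRNA miR-122 gave 812 counts in both samples and 43 to 232 in the others. miR-205 differed between them, at 111 counts in wild type 3 and 1196 in mutant 8, against 649 to 915. These probes were chosen after their values were seen. The 5 cardiac miRNAs together held 10.98% of mouse miRNA counts in wild type 3 and 11.8% in mutant 8, and at most 0.178% in any other sample.

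The repeat lanes of samples 1, 5 and 6 show how far the same RNA can read apart. In the higher-background lane of each, miR-19a read lower by a mean of -0.39 on the log2 scale and miR-19b by -0.36. The other cluster probes moved less, with means of -0.15 for miR-18a, -0.09 for miR-20a and miR-20b (1 pair positive) and -0.05 for miR-106a and miR-17. Of 189 kept probes, 109 (57.7%) moved the same way in all 3 lane pairs, where independent errors would give 25%.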
